A study of Homo sapiens with 2 samples.

How the data were processed

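RNA from 2 cultures of human iCell-CMs was measured on Affymetrix 3' expression arrays, 1 array per group. Biotin-labelled aRNA was made from 150 ng total RNA, per the labels' protocols. The array labels, EGFP and KCNJ2, set the groups. No sample was left out. Because each group has 1 culture, no test across cultures was made, and the number of arrays limits the precision.

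The deposited values are log2 signals per probe set, and the log2 scale was read from the values. Their antilogs have a 2% trimmed mean of 500 on both arrays, the form that global scaling of MAS5 signals takes. MAS5 and R 3.0.1 are named without their role, per the submitters' processing notes. Background correction, detection calls and the genome build of the probe sets are not given in the sources used here. The medians were 6.16 for the EGFP-labelled array and 6.23 for the KCNJ2-labelled array. Exact zeros, which appear to be antilogs set to a floor of 1, numbered 186 and 125. MAS5-type signals vary widely at low levels, so the low end of the scale is the least precise.

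Each array held 54675 probe sets, of which 62 were controls. Names came from a table of the platform's annotation that lists 42898 probe sets. Of these, 41097 have 1 gene symbol and 1801 have several; 11715 non-control probe sets are unnamed here. Entrez identifiers matched current gene records for 41043 of the single-symbol probe sets and 54 kept the table's name. Probe sets with several symbols were named to no gene. Coordinates are not given, since the sources name no build. Genes that tell a donor's sex were left out.

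A gene was represented by its probe set with the highest mean log2 signal, and kept where that mean was at or above the median of all non-control probe sets, 6.08. The difference is the KCNJ2-labelled minus the EGFP-labelled log2 signal on the deposited scaling. A gene was counted as higher or lower at a log2 difference of at least 1. The measurement spread compares these log2 differences between the 2 strongest expressed probe sets of each gene. It is the SD, across genes, of the gap between the 2, divided by the square root of 2. It was 0.38 over 6012 genes, and 0.55, 0.38, 0.31 and 0.22 from the lowest to the highest of 4 equal bins of signal. It covers probe set and hybridisation error, not differences between cultures. Of 216 genes counted as 2-fold by the chosen probe set with a second one expressed, the second had the same sign in 178 (82.4%, against 63.7% over all genes with 2 or more expressed probe sets) and was also 2-fold in 73.

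Before the data were examined, 42 gene lists were fixed. They cover ion channels and transporters, calcium handling, contractile and cardiac identity genes, cardiomyocyte subtypes, other cell types, stress and antiviral responses, signalling, metabolism, translation and proliferation. Each list's median difference was set against 10000 random lists of the same size, matched on signal in 20 bins, and a list stands apart below the 2.5th or above the 97.5th percentile. Lists with fewer than 5 expressed members were not tested.

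The rule for named genes was also fixed then. It takes KCNJ2, and up to 12 genes each way with at least 2 expressed probe sets that all pass 2-fold in the same direction. It adds 8 genes each way with 1 expressed probe set, and up to 3 highest and 3 lowest members of each list. Of the 263 genes this takes, 100 also have probe sets below the filter, which were not used, and in 51 at least 1 of these has the opposite sign. Alternatives were median centring, quantile normalization, no filter, only signals above the 75th percentile, low signals raised to the median of all signals, the mean of a gene's probe sets, leaving out probe sets that can bind several transcripts, removal of the trend with signal level by lowess with a span of 0.3, a 3-fold threshold and list means. After the data were seen, scaling on the spike-in controls and lists without shared members were added. Spike-in controls set to equal means here that 1 constant shift of every gene brings the controls' median difference to 0.

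The steps were tested on simulated data for this comparison, over 12688 genes. Changes of 1.5 on the log2 scale were called in 94% of cases and changes of 2.5 in 100%. Among 12463 unchanged genes 2.30% were called. The glycolysis list was shifted by 0.6, and of 40 other lists 1 stood apart. These other lists can hold some of the changed genes. The simulated noise was normal and independent between probe sets, with the measurement spread as its SD. It held no differences between cultures and no genes that vary together. These values are therefore not false-call rates for the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.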

Results

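Gene expression was compared between human cardiomyocytes infected with an adenovirus for EGFP-KCNJ2 and the same cells infected with an adenovirus for EGFP, the green fluorescent protein used as the control. KCNJ2 encodes Kir2.1, the inward rectifier potassium channel that holds the resting membrane potential of ventricular cardiomyocytes. The cells were iCell-CMs, commercial cardiomyocytes differentiated from induced pluripotent stem cells. They were cultured for 4 days, infected at 100 MOI for 24 h at replating with 250000 cells per well, and collected 4 days after replating. Each group had 1 Affymetrix expression array, so differences between the 2 arrays have no replicate check and no p-value. Values are log2 signals as the authors deposited them, and every difference is the KCNJ2-labelled array minus the EGFP-labelled array.

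The KCNJ2 transcript did not separate the arrays. Its probe set 206765_at gave a log2 signal of 8.95 on the EGFP-labelled array and 8.82 on the KCNJ2-labelled array, a difference of −0.14. The spread between probe sets of one gene had an SD of 0.38 at this signal level, so the difference was smaller than the measurement spread. With the spike-in controls set to equal, its sign turned, to 0.08. Whether this probe set lies in the part of KCNJ2 that the virus carries is not known here, so its signal checks neither the labels nor the overexpression. All directions given here therefore rest on the array labels. Of the 7 expressed inward rectifier channel genes, KCNJ4, a relative of KCNJ2, differed by −1.03, and KCNJ14 had a difference of 0.78. KCNJ5, a subunit of the acetylcholine-gated channel, differed by 0.41 in the strongest of its 5 expressed probe sets, which ranged from −0.29 to 0.41, with a mean of 0.045. The list's median of −0.14 lay at the 19.5th percentile of random gene lists, and was −0.38 with no filter or with only signals above the 75th percentile, within the range.

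Across 12688 expressed genes the arrays were similar, with a Pearson r of 0.969 across genes, which are not independent replicates. The median difference was 0.02. On the KCNJ2-labelled array, 417 genes were at least 2-fold higher and 384 were at least 2-fold lower, together 6.31% of expressed genes. The hybridisation spike-in controls were lower on the KCNJ2-labelled array by a median of −0.22, in 16 of 18 probe sets. Setting their median difference to 0 by 1 constant shift moves the median difference of genes to 0.24. It gives 755 genes higher and 224 lower, so 77.1% of these genes are on the higher side against 52.1% as deposited. The controls differed by −0.50 to 0.16, so 1 shift does not make them all equal. Their lowest signal was 10.84, so the shift is unchecked at lower signals. Differences are given here on the deposited scale. Of the RNA integrity controls, the GAPDH 3' probe set exceeded the 5' probe set by 0.24 on the EGFP-labelled array and 0.19 on the other, and the ACTB 3' probe set exceeded its 5' probe set by 0.22 and 0.48, a change of 0.25.

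**Figure D1:**
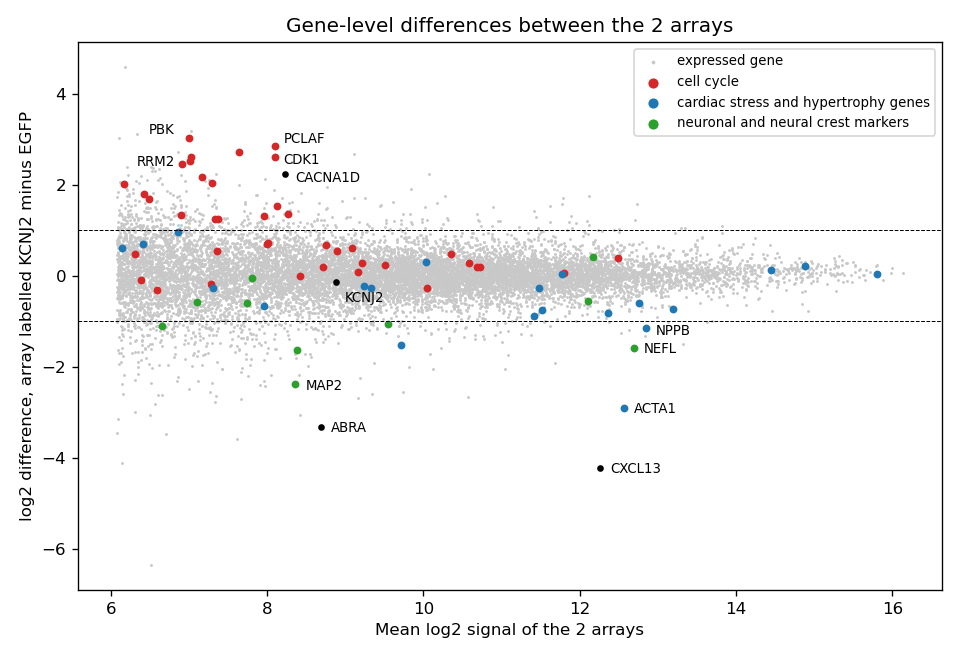
Each point is 1 of 12688 expressed genes, with the mean log2 signal of the 2 arrays on the x axis and the log2 difference (KCNJ2-labelled minus EGFP-labelled) on the y axis; dashed lines mark 2-fold. Cell cycle genes (red) lie mostly above 0 at low signals, neuronal and neural crest markers (green) mostly below 0, and ACTA1 (−2.90) and CXCL13 (−4.22) are low at high signals, while KCNJ2 lies at −0.14.

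Genes with several probe sets have more than one measurement of their difference, though in the same RNA and not always by independent probes. Among 6012 genes with at least 2 expressed probe sets, 26 were at least 2-fold higher and 29 at least 2-fold lower by every one of them. CDK1, the kinase that drives entry into mitosis, was higher by 2.60 (6.07-fold) and by at least 1.52 in each of its 3 expressed probe sets. RRM2, a subunit of ribonucleotide reductase, was higher by 2.52, and CDCA3, a cell division gene, by 1.43. Both RRM2 signals on the EGFP-labelled array, 5.76 and 5.04, were under the median of all signals. With low signals raised to that median the RRM2 difference was 2.53, then by its other probe set. CACNA1D, the pore subunit of the L-type calcium channel Cav1.3, was higher by 2.24, from 7.11 to 9.35. The guidance factor SLIT3 differed by 1.91, the laminin subunit LAMA2 by 1.75, the insulin-like growth factor binding protein IGFBP3 by 1.71, and TGFBR3, a co-receptor for TGF-beta, by 1.53. The sulfotransferase CHST1 differed by 1.76, ANKRD29 by 1.54, AHNAK by 1.36 and EXOG, a mitochondrial nuclease, by 1.35.

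The lower genes of this kind were led by MELTF, a cell surface iron-binding protein, at −3.57, although its signal of 5.82 on the KCNJ2-labelled array was under the median of all signals. The protocadherin PCDH17 was lower at −2.66 and the natriuretic peptide clearance receptor NPR3 at −2.56. PRRX1, a mesenchymal transcription factor, was lower at −1.91, and RRAD, a small GTPase that restrains L-type calcium channels, at −1.73. The metallothionein MT1F differed by −1.59, though both of its probe sets can bind several transcripts. The neurofilament NEFL differed by −1.57, the hyaluronan synthase HAS2 by −1.48 and DUSP6, a phosphatase that inactivates ERK, by −1.46. The transcription factor ATOH7 differed by −1.72, CTC-338M12.4 by −1.72 and FAM218A by −1.47.

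Genes measured by a single expressed probe set reached larger differences. CXCL13, a chemokine for B cells, was lower at −4.22 (18.6-fold), from 14.37 to 10.15. ABRA, an actin-binding protein of striated muscle, was lower at −3.31, while its other probe set, below the filter on low signals, differed by −0.20. RPPH1, the RNA of ribonuclease P, was lower at −3.06. PCLAF and NUSAP1, genes of DNA replication and of the mitotic spindle, were higher by 2.85 and 2.72, while the other PCLAF probe set, below the filter, differed by −0.98. P2RY14, a receptor for UDP-glucose, was higher by 2.67. For others of this kind 1 of the 2 signals was under the median of all signals, so the size is loosely measured. MFAP4, a microfibril protein, was higher by 4.57 as deposited and by 2.27 with low signals raised to that median. The same step took STX17-DT from 3.17 to 2.41, DDX19B from 3.11 to 1.69, the mitotic kinase PBK from 3.03 to 2.32 and CASKIN1 from 3.02 to 1.41, and CASKIN1 probe sets below the filter differed by −0.67 and −0.87. Among lower genes it took ZNF143-AS1 from −6.35 to −3.50, PARTICL from −4.10 to −1.99, TSKU-AS1 from −3.46 to −1.62, SPATA32 from −3.13 to −1.46 and SEMA5B from −3.06 to −1.84.

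Gene lists were set against random lists of equal size and signal level. Of 41 lists with at least 5 expressed members, 11 had a median outside the central 95% of random lists. For lists of randomly picked genes the expected number is 2.05. The fixed lists share members, and related genes can vary together between any 2 cultures, so this comparison does not measure an excess. The percentiles describe these 2 arrays only.

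Cell cycle genes were higher on the KCNJ2-labelled array. The median difference of 40 expressed members was 0.69, above all 10000 random lists. Of these members, 36 had positive differences, 18 were at least 2-fold higher and 0 at least 2-fold lower. Of 11 members with several expressed probe sets, 9 were higher in all of them, CDK1 and RRM2 included. Against this, the proliferation marker MKI67 differed by −0.18, the centromere histone CENPA by −0.31 and E2F8 by −0.27. The MKI67 probe sets below the filter differed by 0.48, −2.40 and 2.53. Replication-dependent histones had a median of −0.06 at the 23.7th percentile, and −0.34, below the range, without probe sets that can bind several transcripts. The sizes belonged to weakly expressed members. Among 14 members with signals above the 75th percentile the median was 0.25, at the 98.8th percentile, and 0 were 2-fold higher. Without probe sets that can bind several transcripts, and also with no filter, the median was 1.24, and the list mean was 1.06.

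Markers of other cell types differed in opposite directions. Neuronal and neural crest markers were lower, with a median of −0.83 over 10 genes, below all random lists, and 5 were at least 2-fold lower. MAP2, a neuronal microtubule protein, differed by −2.36, the neurofilaments NEFM and NEFL by −1.63 and −1.57, and the tubulin TUBB3 by −0.55. NCAM1, also expressed in heart cells, differed by 0.41, and its 7 expressed probe sets ranged from −1.44 to 0.70. Smooth muscle markers were higher, with a median of 0.47 over 15 genes at the 99.98th percentile, and 3 were at least 2-fold higher. MYH11, the smooth muscle myosin, differed by 1.24, or 0.75 with low signals raised, LMOD1 by 1.18, or 0.97 with the mean of its probe sets, and ACTA2, smooth muscle actin, by 0.70, whereas calponin CNN1 differed by −0.69 and desmin DES by −0.62. With signals above the 75th percentile only, the smooth muscle median was 0.08 and lay within the random range, and the list mean was 0.31. Of the smooth muscle markers, 6 are also on another list, and several are expressed by cardiomyocytes in culture. Fibroblast and matrix genes lay within the random range at −0.09, with COL1A1 at 1.05, or 0.77 with the mean of its probe sets, and LUM at −1.45 in its strongest probe set and −0.92 in another. Endothelial markers had a median of 0.66 over 6 genes and epicardial markers 0.22 over 6, both within the range, with the epicardial transcription factor WT1 at 2.31, or 1.52 with low signals raised. Immune cell markers (0.44) and hepatic and endodermal markers (−0.55) had 5 expressed genes each and lay within the range. Pluripotency markers had only 4 expressed genes, which differed by −0.66 for DNMT3B, −0.42 for LIN28B, −0.16 for PODXL and 0.14 for GDF3.

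Cardiac stress and hypertrophy genes were lower on the KCNJ2-labelled array. Their median was −0.26 over 21 genes, at the 0.01st percentile, with 13 negative differences and 3 genes at least 2-fold lower. ACTA1, skeletal actin, was lower at −2.90 (7.49-fold), from 14.01 to 11.11, and NPPB, which encodes the natriuretic peptide BNP, at −1.15. The calcineurin regulator RCAN1 differed by −0.88 and XIRP1 by −0.75. Endothelin EDN1 differed by 0.97 and MYC by 0.69, or 0.57 with low signals raised. Genes of the ATF4 and amino acid response had a median of −0.25 over 27 genes at the 0.08th percentile. ATF3 differed by −1.51 in its strongest probe set and −0.69 in another, and CHAC1 by −1.15, or −0.92 with low signals raised, whereas the serine synthesis enzyme PHGDH differed by 0.74. Without probe sets that can bind several transcripts, the ATF4 median was −0.19 at the 2.74th percentile, and the call was lost. Of the expressed stress genes, 16 are also on another list. The stress median was −0.43 with only signals above the 75th percentile and −0.46 without probe sets that can bind several transcripts. With the spike-in controls set to equal, the median of the stress genes was −0.04 and that of the ATF4 list −0.03.

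Activity-dependent immediate early genes, which respond to calcium and growth signals, had a median of −0.21 over 26 genes at the 0.39th percentile, which turned to 0.011 with the spike-in controls set to equal. The transcription factor KLF4 was lower at −2.54, or −2.34 with low signals raised, ATF3 at −1.51 and DUSP6 at −1.46. FOS differed by 0.30, KLF10 by 0.51 and EGR4 by 0.63. The call was lost with the mean of all probe sets, at −0.09, and without probe sets that can bind several transcripts, at −0.04. It was also lost without the members shared with the cardiac stress and ATF4 lists, at −0.087. The list mean was −0.33, and the median with only signals above the 75th percentile was −0.31.

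Sodium, calcium and pacemaker channel genes had a median of 0.33 over 15 genes at the 99.0th percentile. CACNA1D was higher by 2.24, while CACNA2D2 differed by 0.84 and SCN8A by 0.87, or 0.69 with low signals raised. The SCN8A probe sets below the filter differed by −0.64, 1.74, −2.10 and −1.10. The sodium channel beta subunits SCN4B, SCN2B and SCN3B differed by −1.31, −1.14 and −0.56, with SCN4B at −1.23 with low signals raised. With the list mean in place of the median the call was lost, at 0.26, and with only signals above the 75th percentile the median was 0.61. Voltage-gated and two-pore potassium channel genes lay within the random range at −0.14, with KCNA4, a subunit of transient outward current, at −1.39, and KCNA5 at 1.46, or 1.11 with low signals raised. The sodium-potassium pump and ion transporter genes had a median of −0.20 over 18 genes at the 0.82nd percentile, which turned to 0.022 with the spike-in controls set to equal. FXYD5, a pump regulator, differed by −1.05, SLC4A2 by −0.81 and SLC4A7 by 1.23 in the strongest of its 3 expressed probe sets and by 0.74 and 0.01 in the others, with a mean of 0.66. The call was lost with the list mean, at −0.11, and with only signals above the 75th percentile, at −0.16.

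Cardiac transcription factors had a median of 0.20 over 25 genes at the 98.8th percentile, and 20 had positive differences. HOPX differed by 1.21, TBX20 by 1.09, or 0.48 with low signals raised, and NFATC1 by 1.18, with −1.20 and −2.57 in 2 of its 3 probe sets below the filter, whereas MEF2C differed by −1.34, with −0.73 in its other probe set, and PPARGC1A, a regulator of mitochondrial genes, by −0.78. MEF2D differed by 1.59 in one probe set and by −0.04 in another. The call was lost with the mean of all probe sets, at 0.12, with only signals above the 75th percentile, at 0.17, and without probe sets that can bind several transcripts, at 0.20. Ventricular markers had a median of 0.22 over 15 genes at the 97.7th percentile. Among them HEY2 differed by 0.78, LBH by 1.11 and PRDM16 by 1.14, while the ventricular myosin light chain MYL2 differed by −0.78. This call was lost in 5 of the 8 alternatives that can move a percentile, and the median was 0.05 with signals above the 75th percentile only, 0.15 with the trend with signal level removed and 0.63 without probe sets that can bind several transcripts. Of the ventricular markers, 10 are also on another list. Atrial markers (0.15) and nodal markers (0.24) lay within the random range, though the nodal list mean, 0.41, stood above it, as did its median of 0.36 without probe sets that can bind several transcripts. GJA5, the gap junction protein connexin 40, was higher by 2.12, with −1.55 in its probe set below the filter, and sarcolipin SLN differed by −1.61, or −1.12 with low signals raised.

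The contractile genes did not move together. The 36 sarcomere genes had a median of 0.05, within the random range, but a mean of −0.20, below it. The median turned negative in 4 alternatives, to −0.02 with quantile normalization, −0.015 with the trend with signal level removed, −0.06 with the mean of all probe sets and −0.08 without probe sets that can bind several transcripts. Troponin TNNI3 differed by −1.22, titin-cap TCAP by −0.92 and NRAP by −0.92, while tropomodulin TMOD1 differed by 1.03, or 0.94 with the mean of its probe sets, and MYH6 by 0.33. Fetal-type contractile isoforms had a median of 0.21 at the 97.4th percentile, just within the range, and left it in 5 of 8 alternatives. They lay above it in 4, with percentiles up to 98.3, and below it with the list mean, at −0.19. Calcium handling genes lay within the range at −0.03 and intercalated disc genes at 0.13, or −0.07 with the mean of all probe sets. In the calcium handling list CASQ1 differed by −1.31, the sarcalumenin gene SRL by 0.90 and JPH2 by 0.59.

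All 33 expressed ribosomal protein genes had positive differences as deposited, against 31 with median centring, 29 with the trend with signal level removed and 27 with quantile normalization. They had a median of 0.17 at the 99.6th percentile and 0 members reaching 2-fold. RPS3 differed by 0.45 and RPL24 by 0.44. With quantile normalization RPS16, RPL10A and RPL3 turned to −0.09, −0.08 and −0.07. The call was lost with quantile normalization, where the median was 0.08, and without probe sets that can bind several transcripts, at 0.20. With the trend with signal level removed the median was 0.10.

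**Figure D2:**
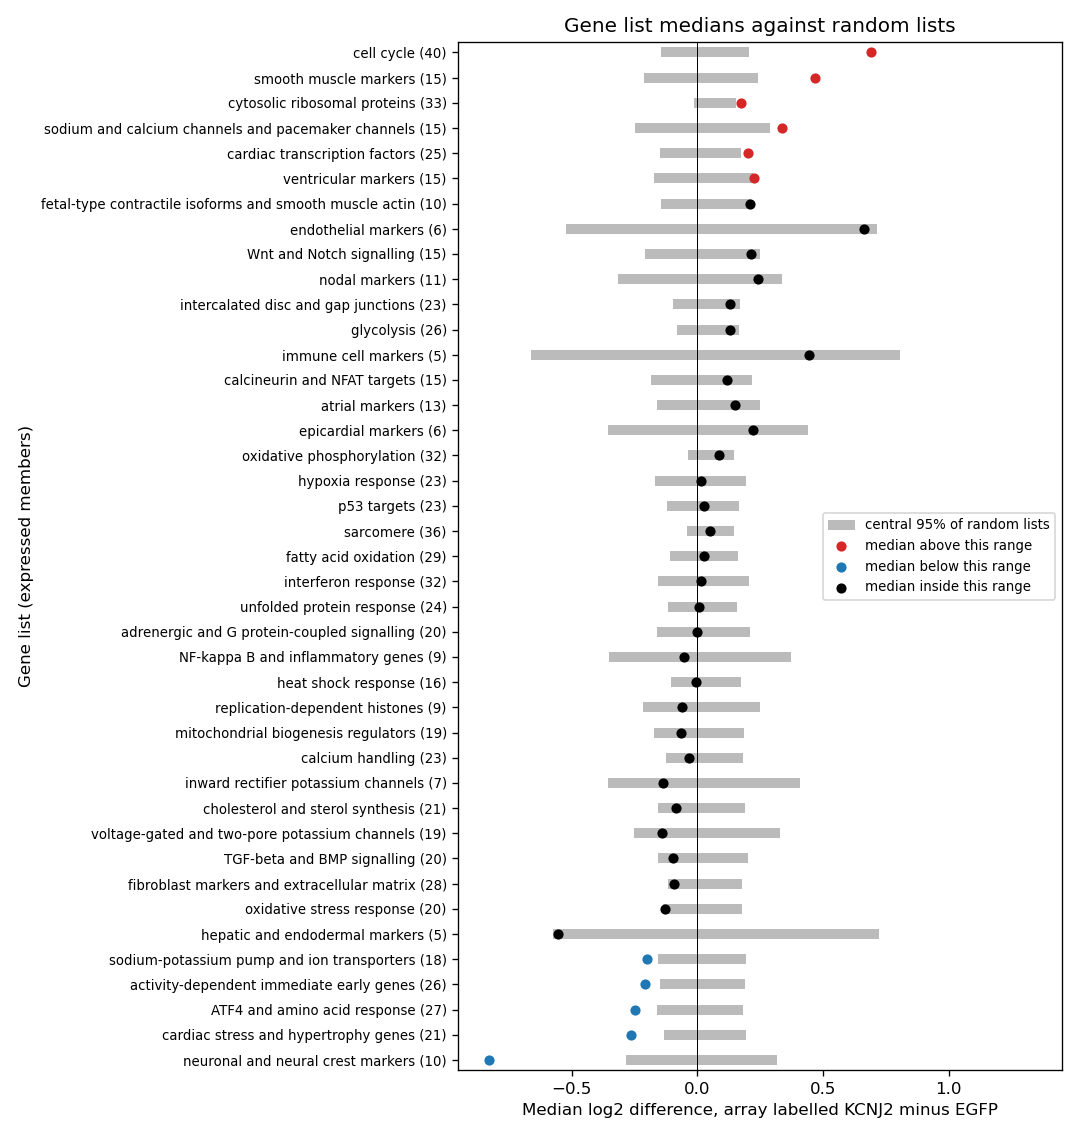
Median log2 difference (KCNJ2-labelled minus EGFP-labelled, x axis) of 41 gene lists (y axis, number of expressed members in parentheses), with grey bars for the central 95% of 10000 random lists of equal size and signal level. Cell cycle (0.69) lies farthest above its bar and neuronal and neural crest markers (−0.83) farthest below; the medians of the activity-dependent and of the pump and transporter lists turn to 0.011 and 0.022 with the spike-in controls set to equal.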

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

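The use of list medians and probe sets as tests of an explanation, the second probe sets and the lists without shared members were chosen after the values were seen. The other list medians given under this heading were planned.

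A pair of probe sets annotated to RAP1A, a small GTPase, were picked out for a difference of over 16-fold, a size set after the data were seen. Neither is the probe set chosen for RAP1A, but both enter the alternative that takes the mean of a gene's probe sets. Probe set 1555340_x_at went from 3.11 to 11.22, a difference of 8.11, and 1555339_at from 4.37 to 12, a difference of 7.63. Both signals on the EGFP-labelled array were under the median of all signals, 6.20, and raising them to it leaves differences of at least 5.02 (32.5-fold) and 5.81 (55.9-fold). A higher RAP1A transcript level is argued against, since the other 2 expressed RAP1A probe sets, 202362_at and 228548_at, had a median difference of −0.063. Whether these probes bind another sequence, transcribed with 1 virus only, stays open, since low signals on the EGFP-labelled array, at most 4.37, follow largely from picking the pair for its difference and no probe sequences were used here, and so does a RAP1A form that the other probe sets do not measure. The annotated RNA may be a fluorescent biosensor construct, which was not checked, and the probes could then detect a variant of GFP; both viruses carry EGFP, so why the EGFP-labelled array lacks the signal, and with it whether the array labels are right, stays open too.

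The higher cell cycle genes had a median difference of 0.69. Noise of low signals is argued against as the whole cause for 11 members by their second probe sets. Their median difference was 0.57, at the 99.9th percentile of second probe sets of random genes at the same signal levels. Of these 11, 3 were at least 2-fold higher, against 18 of all 40 members by the chosen probe set. Members without a second expressed probe set are not covered, and probe sets of 1 gene are not always independent. A smaller share of cardiomyocytes with more of every other cell type would raise all lists of other cell types. The neuronal and neural crest median was −0.83, while smooth muscle markers stood at 0.47. Both medians were known when this explanation was written down, so they describe the arrays and are no separate test. They speak against it only as far as these markers are specific to other cells here, which was not checked. Sarcomere genes had a median of 0.05, within the random range, and a mean of −0.20, below it, so they do not settle the share. A smaller share of cardiomyocytes with more of only some other cell types stays open, as does a larger share of 1 dividing cell type. An effect of the virus and a difference between cultures cannot be told apart with 1 array per group.

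The lower activity-dependent and cardiac stress genes share members, so the lists are not independent. Without members found on 2 or more of the 3 stress lists, the activity-dependent list moved to the 13.3rd percentile with a median of −0.09, consistent with shared members carrying its difference. The cardiac stress list stayed apart at the 0.85th percentile with a median of −0.22. Of its 15 remaining members, 8 were lower and 7 higher. With so even a split the median rests on few genes, so this argues only weakly against shared members as the whole cause there. The interferon response list did not stand apart, with a median of 0.014 at the 47.2nd percentile, inside its random range of −0.16 to 0.21. Its members went both ways, with an SD of 0.55, which is a spread between genes and not the precision of the median. The list as a whole was therefore not lower. A weaker response to viral infection stays open, since it may lower only some members. An effect of the channel and a difference between cultures cannot be told apart with 1 array per group.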

How the results depend on the processing

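No paired analysis was possible because each group has 1 array. The spike-in scaling and the lists without shared members were added after the data were seen. The KCNJ2 difference stayed within its spread in all alternatives, from −0.16 to 0.08. The counts of genes at least 2-fold higher and lower went from 417 and 384 to 2440 and 2003 with no filter and to 90 and 103 with only signals above the 75th percentile, because the genes tested change and low signals vary most. They were 93 and 109 at a 3-fold threshold, by construction, and 755 and 224 with the spike-in controls set to equal. In the other alternatives they ranged from 325 to 411 and from 328 to 407. The number of lists apart went from 11 to 7 with only signals above the 75th percentile, where fewer members are left, and was 9 to 13 otherwise. The spike-in scaling, which like median centring shifts each gene alike and moves no percentile, reversed the medians of the activity-dependent list, to 0.011, and of the sodium-potassium pump and transporter list, to 0.022; both signs turn by construction, since each list moved up by the same amount. Cell cycle and cardiac stress kept their calls in all 8 alternatives that can move a percentile and were fixed before the data were examined, neuronal markers in the 7 that left enough members, ATF4, smooth muscle and sodium and calcium channel lists in 7 of 8, immediate early, ribosomal and pump lists in 6, cardiac transcription factors in 5 and ventricular markers in 3. Of the 30 lists within the random range, 9 left it in at least 1 of these alternatives, the fetal-type contractile isoforms in 5, the glycolysis, nodal and hepatic lists in 2 each, and the TGF-beta, adrenergic, oxidative stress, histone and sarcomere lists in 1 each, and the medians or means of 14 turned sign. No named gene at least 2-fold apart changed sign in any alternative that gave it a value. Some of these genes have no value without probe sets that can bind several transcripts. Most alternatives keep the same probe set or shift each gene alike, so few could turn a sign. Single expressed probe sets can still have the opposite sign, as for SREBF2 at 1.20 and −0.28. Low signals limit what the arrays can resolve.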

Other observations

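Metabolic and stress lists that the comparisons above do not describe lay mostly within the random range. Glycolysis genes had a median of 0.13 at the 90.5th percentile. The regulatory enzyme PFKFB4 differed by 2.18, or 1.29 with low signals raised, muscle phosphoglycerate mutase PGAM2 by 1.74 and aldolase ALDOC by 1.55, and the list's mean of 0.29 stood above the range, as did its median of 0.19 with no filter, whereas without probe sets that can bind several transcripts the median turned to −0.05. Fatty acid oxidation (0.02), oxidative phosphorylation (0.08), mitochondrial biogenesis regulators (−0.07), cholesterol and sterol synthesis (−0.08) and hypoxia response genes (0.01) lay within it. The fatty acid transporter CD36 differed by −1.32 in the strongest of its 3 expressed probe sets and by −0.64 and −0.89 in the others, with a mean of −0.95, and the sterol regulator SREBF2 by 1.20 in the strongest of its 3 expressed probe sets and by 0.09 and −0.28 in the others, with a mean of 0.34. Heat shock (−0.01), unfolded protein response (0.01), p53 target (0.03), NF-kappa B (−0.05) and interferon response genes (0.01) were also within the range. The NF-kappa B median turned to 0.26 with only signals above the 75th percentile, and that of sterol synthesis to 0.11 without probe sets that can bind several transcripts. EIF2AK3, the kinase PERK, differed by −1.26 and the antiviral factor IRF7 by 1.23, while HERC5 and TAP1, also of the interferon list, differed by −1.17 and −0.85.

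Signalling lists were within the range too, at −0.10 for TGF-beta and BMP, 0.21 for Wnt and Notch, 0.12 for calcineurin and NFAT targets and 0.00 for adrenergic and G protein-coupled signalling. The calcineurin median turned to −0.12 with only signals above the 75th percentile. The TGF-beta median was −0.20 with the mean of all probe sets and the adrenergic median −0.17 with low signals raised, both below the range. The Notch ligand JAG1 differed by −1.19 and was lower in all 4 expressed probe sets. Its probe sets below the filter differed by 2.20 and −1.56. NOTCH3 differed by 1.34, or 1.14 with low signals raised. INHBA, an activin subunit, differed by −1.28, the phosphodiesterase PDE3A by −1.45 and the adenylyl cyclase ADCY5 by 1.49. The oxidative stress list had a median of −0.13 at the 3.02nd percentile, and its mean of −0.28 lay below the range. Its lowest members were metallothioneins. All 6 expressed metallothionein genes, a group chosen after its values were seen, were lower, 4 of them by at least 2-fold, with a median of −1.26. Their sequences are similar, so the probe sets are not independent.

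PEG10, an imprinted gene chosen after its values were seen, differed by 2.23 (4.70-fold) in the probe set with the stronger signal and by 0.31 in the other. The hypothesis of a shift of imprinted genes as a group was tested after the fact on 17 other expressed imprinted genes. Their median was −0.018 with an SD of 0.48 between genes, which argues against a shift of the size seen for PEG10; smaller shifts are not excluded.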
